A study of Arabidopsis thaliana with 42 samples.

How the data were processed

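Leaf RNA of Arabidopsis thaliana was hybridized as biotin-labelled cRNA made from total RNA to 42 arrays, in 14 groups of 3 biological replicates. The groups were Col, eds1 and rsw3 leaves at 0 h (mock) and at 2, 10 and 24 h after elf18, and Col and eds1 leaves at 24 h after flg22. The deposited values are log2 values made with RMA, per the submitters' processing notes, and no version of RMA or of the probe annotation is named. The 2 deposited tables hold the same values, with a largest difference of 5e-09. Each has 16383 rows, of which 370 are control probe sets and 16013 carry a locus name (7727 on chromosome 1, 4987 on chromosome 2 and 3299 on chromosome 3). Values run from 1.14 to 13.89 with 0 missing.

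The row names stood 1 row above the values they belong to in both tables, and each value row was given the name of the row above. This was checked in 5 ways. The median level of 23 photosynthesis genes was 6.06 with the names as deposited and 11.67 with the names moved by 1 row, and 5 against 20 of them lay in the top 10%. For 106 pairs of neighbouring probe sets of the same gene, the median correlation over the arrays was 0.15 against 0.905. Protein-coding loci stood above loci of other kinds with an area under the curve of 0.662 against 0.837, and in 17 of 17 windows of 1000 rows the fit was best at 1 row. The 8 early pattern response genes changed at 2 h after elf18 in Col by a median of -0.04 against 1.91. The first value row has no name, the last name (AT3G29480) no value, and the reason for the displacement is not known. This choice was made after the values were seen.

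Rows named for several loci (50) stayed in the fit and were not counted. For the 72 genes with more than 1 probe set the brightest was used, leaving 15856 genes. Symbols came from the TAIR10.1 annotation, in which 15676 genes matched and 5645 had a symbol other than the locus. Since the values end within chromosome 3, many immune genes, the receptors of both peptides among them, are not analysed here. EDS1, RSW3 and PBS3 had 0 rows.

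Array medians were 4.30 to 4.43, 25th percentiles 2.88 to 3.26, and standard deviations 2.08 to 2.30 (log2). Replicates correlated at 0.978 to 0.992, no 2 arrays were identical, and the first 2 principal components held 27.9% and 23.9% of the variance. The residual standard deviation of an array was 0.167 to 0.297. Array 2 of eds1 at 24 h after elf18 stood apart, with the highest 25th percentile, the lowest standard deviation and the highest residual standard deviation. Replicate numbers did not pair the arrays: deviations from the group means correlated at -0.00866 on average between arrays of the same number and 0.00463 between others.

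Differences were estimated with limma 3.58.1 in R 4.3.3, from 1 linear model of 14 group means over all 42 arrays with moderated variances, without a replicate block. In 29 comparisons a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. Differences in response are the change from 0 h in a mutant minus that in Col. The p-values of this fit rest on the spread between biological replicates, pooled over all 14 groups. The labels do not say whether the replicates came from separate plantings or experiments, so that spread may not be covered. The comparisons of eds1 and rsw3 with Col share the Col arrays. Methods, comparisons, gene lists and the rule for naming genes were fixed before the data were examined.

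20 gene lists were tested with fry of limma, adjusted over the lists of a comparison, beside camera with a preset correlation of 0.01 and with an estimated correlation. The lists are salicylic acid synthesis and EDS1 signalling, salicylic acid responsive genes, the N-hydroxypipecolic acid pathway, pattern receptors and early signalling, early pattern response genes, tryptophan, camalexin and indole glucosinolates, jasmonate, ethylene, abscisic acid and dehydration, endoplasmic reticulum folding and quality control, cell wall and cellulose synthesis, photosynthesis, flavonoids and anthocyanins, the circadian clock, senescence, and markers of guard cells, phloem, trichomes and roots, and reference genes. A further list of 21 low-oxygen genes was written after the data were seen.

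Genes named in each comparison are taken from the top of the ranking by absolute log2 difference, up to 8 per direction, among called genes with a symbol and non-overlapping replicates (for differences in response, among called genes), together with the largest members of each list. Where only some of them are given, the text says how they were picked, and loci without a symbol were chosen after their values were seen. Non-overlap of 3 against 3 arrays happens by chance in 10% of genes.

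The alternatives were quantile normalization, centring of each array on its median, leaving out the dimmest 30% of probe sets, the mean of a gene's probe sets, the other deposited table, a replicate block, a fit of only the arrays of a comparison, a trend with robust variances, array weights, a 2-fold change as well, and leaving out each array in turn. With 2 arrays left in a group the spread still comes from all groups. The names as deposited, the 25th percentile of each array as a covariate and a fit without array 2 of eds1 at 24 h after elf18 were added after seeing the data. The method was tested on simulated data for 2 of the comparisons. Arrays measure relative RNA levels only.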

Results

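RNA of Arabidopsis thaliana leaves was measured on 42 arrays, in 14 groups of 3 biological replicates each. Leaves of the wild type Col-0 (Col) and of the mutants eds1 and rsw3 were sampled at 0 h as mock-treated controls and at 2, 10 and 24 h after elf18, and leaves of Col and eds1 also at 24 h after flg22. elf18 is a peptide of bacterial elongation factor Tu and flg22 a peptide of bacterial flagellin, and both set off pattern-triggered immunity through receptors on the cell surface. EDS1 is a lipase-like regulator of plant immunity, and RSW3 is the alpha subunit of glucosidase II, which takes part in the folding of glycoproteins in the endoplasmic reticulum. The titles of the flg22 arrays differ in style from the others and give eds1 as eds1_2, while their sources read eds1, and the labels do not say whether the line is that of the other eds1 arrays. No group received mock after 0 h, so in every comparison with 0 h the peptide and the time of sampling changed together. Levels are log2 RMA values, with correlations between replicates from 0.978 to 0.992. The number of arrays limits the precision. The p-values rest on the spread between biological replicates pooled over all 14 groups, and not on that of the compared groups alone.

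The values analysed cover chromosomes 1 and 2 and the first part of chromosome 3, as 15856 genes. EDS1, RSW3 and PBS3, whose levels would check the genotype labels or are named in the study's title, lie outside this part and have 0 rows, so the labels could not be checked on them. The row names stood 1 row above their values in the deposited tables, and every gene below carries the name from the row above its values. With the names moved by 1 row, the 23 photosynthesis genes had a median level of 11.67 and 20 of them lay in the top 10% of all rows, against 6.06 and 5 with the names as deposited. Differences below are log2 differences ± SE, levels are log2 means ± SD, with n = 3 arrays per group and adjusted p from limma unless another test is named.

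The response of wild-type leaves to elf18 was measured at 2, 10 and 24 h against the 0 h controls. The receptor kinase gene FRK1 rose by 4.71 ± 0.23 at 2 h, 5.60 ± 0.23 at 10 h and 3.73 ± 0.23 at 24 h, from a level of 2.90 ± 0.22 at 0 h (adjusted p = 1.33e-16, 6.21e-19 and 3.87e-14). IOS1, which encodes another receptor kinase, rose by 4.26 ± 0.17, 4.57 ± 0.17 and 3.72 ± 0.17 at the same times, and the transcription factor gene MYB15 by 4.05 ± 0.29, 4.60 ± 0.29 and 4.38 ± 0.29. The clock genes CCA1 and LHY fell, with changes of -1.79 ± 0.15 and -1.93 ± 0.12 at 2 h and of -4.64 ± 0.15 and -4.47 ± 0.12 at 10 h, and at 24 h LHY was still lower (-0.48 ± 0.12, adjusted p = 0.00204). ICS1, the isochorismate synthase of salicylic acid synthesis, rose by 2.28 ± 0.26 at 2 h and 3.27 ± 0.26 at 10 h, and PR1 was 3.27 ± 0.33 higher at 24 h.

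Of the 15856 genes, 1457 rose and 1908 fell at 2 h, 2179 rose and 2401 fell at 10 h, and 2331 rose and 3063 fell at 24 h. Among the largest rises were AIR12 (4.03 ± 0.15) and MLO12 (3.89 ± 0.16) at 2 h, GSTU11 (5.48 ± 0.29), LURP1 (4.71 ± 0.46) and NIMIN1 (4.68 ± 0.28) at 10 h, and GSTU11 (3.95 ± 0.29) at 24 h. The largest falls among genes with a symbol were ASG4 and GASA6 at 2 h (-3.28 ± 0.21 and -3.28 ± 0.39), FTM1 at 10 h (-5.87 ± 0.30) and GASA6 at 24 h (-4.42 ± 0.39). Chosen after its values were seen, the locus without a symbol AT2G17740 rose by 5.63 ± 0.23, 5.82 ± 0.23 and 5.33 ± 0.23, from a level of 5.48 ± 0.58 at 0 h.

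The gene lists below were tested with limma's fry, with adjusted p over the 20 lists of a comparison. Every list was measured only in part, and counts of genes are of its measured members. Measured were 5 of 17 genes of salicylic acid synthesis and EDS1 signalling, 10 of 19 salicylic acid responsive genes and 10 of 26 clock genes. Among the others were 8 of 22 cell wall, 4 of 20 flavonoid, 2 of 10 senescence and 2 of 7 phloem genes, and 20 of 28 jasmonate genes. At 10 h in Col the 8 early pattern response genes had median 2.21, 7 of 8 genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 1.98e-14, and the 12 genes of pattern receptors and early signalling had median 0.92, 7 of 12 genes higher and 1 lower, 8 and 2 adjusted over the list alone, adjusted p = 1.29e-11, or 0.0566 with an estimated correlation. The 5 genes of salicylic acid synthesis and EDS1 signalling had median 1.57, 5 of 5 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 4.87e-14. The 10 salicylic acid responsive genes had median 2.39, 9 of 10 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 3.19e-19. The 3 genes of the N-hydroxypipecolic acid pathway had median 1.69, 2 of 3 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 2.49e-09, or 0.0566 with an estimated correlation, and the 15 genes of tryptophan, camalexin and indole glucosinolates had median 0.57, 7 of 15 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 1.56e-09, or 0.0566 with an estimated correlation. The 21 genes of endoplasmic reticulum folding and quality control had median 1.09, 20 of 21 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 1.98e-14, led by PDIL1-2 (2.70 ± 0.15) and PDIL2-2 (2.44 ± 0.15).

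Among the lists of growth, light and time, also at 10 h in Col, the 23 photosynthesis genes had median -0.58, 0 of 23 genes higher and 20 lower, 0 and 23 adjusted over the list alone, adjusted p = 4.23e-09, or 0.0688 with an estimated correlation. LHCB4.2 had the largest fall among them, -3.06 ± 0.22, from 12.43 ± 0.05 at 0 h. The 8 cell wall and cellulose synthesis genes had median -0.59, 1 of 8 genes higher and 5 lower, the same counts adjusted over the list alone, adjusted p = 1.03e-08, or 0.0688 with an estimated correlation. The 4 flavonoid and anthocyanin genes had median -0.74, 0 of 4 genes higher and 2 lower, 0 and 4 adjusted over the list alone, adjusted p = 1.24e-08, or 0.0566 with an estimated correlation. The 10 circadian clock genes had median -1.83, 4 of 10 genes higher and 6 lower, the same counts adjusted over the list alone, adjusted p = 6.01e-17, or 0.0955 with an estimated correlation, and ELF4 rose by 3.78 ± 0.16 while CCA1 fell. The 8 ethylene genes had median 0.43, 5 of 8 genes higher and 0 lower, 5 and 1 adjusted over the list alone, adjusted p = 1.9e-06, or 0.146 with an estimated correlation. The 20 jasmonate genes moved both ways, with median 0.06, 5 of 20 genes higher and 5 lower, the same counts adjusted over the list alone, adjusted p = 0.564, and the 6 abscisic acid and dehydration genes had median -0.12, 0 of 6 genes higher and 2 lower, the same counts adjusted over the list alone, adjusted p = 7.05e-06, or 0.264 with an estimated correlation.

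The remaining lists at 10 h in Col were small. The 2 senescence genes had median 0.95, 2 of 2 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 1.09e-05, or 0.131 with an estimated correlation. The 2 phloem markers had median 0.45, 1 of 2 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 3.44e-05, or 0.275 with an estimated correlation, the 4 trichome markers median -0.25, 0 of 4 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 0.0202, or 0.495 with an estimated correlation, and the 4 root markers median -0.35, 0 of 4 genes higher and 2 lower, the same counts adjusted over the list alone, adjusted p = 0.00027, or 0.275 with an estimated correlation. The 5 guard cell markers had median 0.06, 0 of 5 genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.545. The 4 reference genes had median 0.04, 1 of 4 genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.464. By fry 11 lists were higher and 7 lower at 2 h, 10 and 7 at 10 h, and 10 and 6 at 24 h. With an estimated correlation between the genes of a list, 9, 4 and 5 lists passed at these times.

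Some lists were also measured at 2 and 24 h after elf18 in Col, each against 0 h. The endoplasmic reticulum list had a median of 0.53 at 2 h (adjusted p = 1.01e-09) and 0.08 at 24 h (adjusted p = 0.0371, or 0.602 with an estimated correlation). The salicylic acid responsive list had 0.34 at 2 h (adjusted p = 5.73e-06) and 1.27 at 24 h (adjusted p = 1.21e-12), and the early pattern response genes 1.91 (adjusted p = 5.66e-12) and 2.22 (adjusted p = 5.57e-15). The clock list had a median of -0.58 at 2 h (adjusted p = 2.61e-11) and 0.08 at 24 h (adjusted p = 0.119). Jasmonate genes were higher at 2 h (median 0.53, adjusted p = 9.29e-07, or 0.0629 with an estimated correlation) and at 24 h (median 0.70, adjusted p = 6.37e-09, or 0.0711 with an estimated correlation), with CYP94C1 higher by 2.11 ± 0.18 and 2.06 ± 0.18. Times and lists were not tested against each other.

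**Figure D1:**
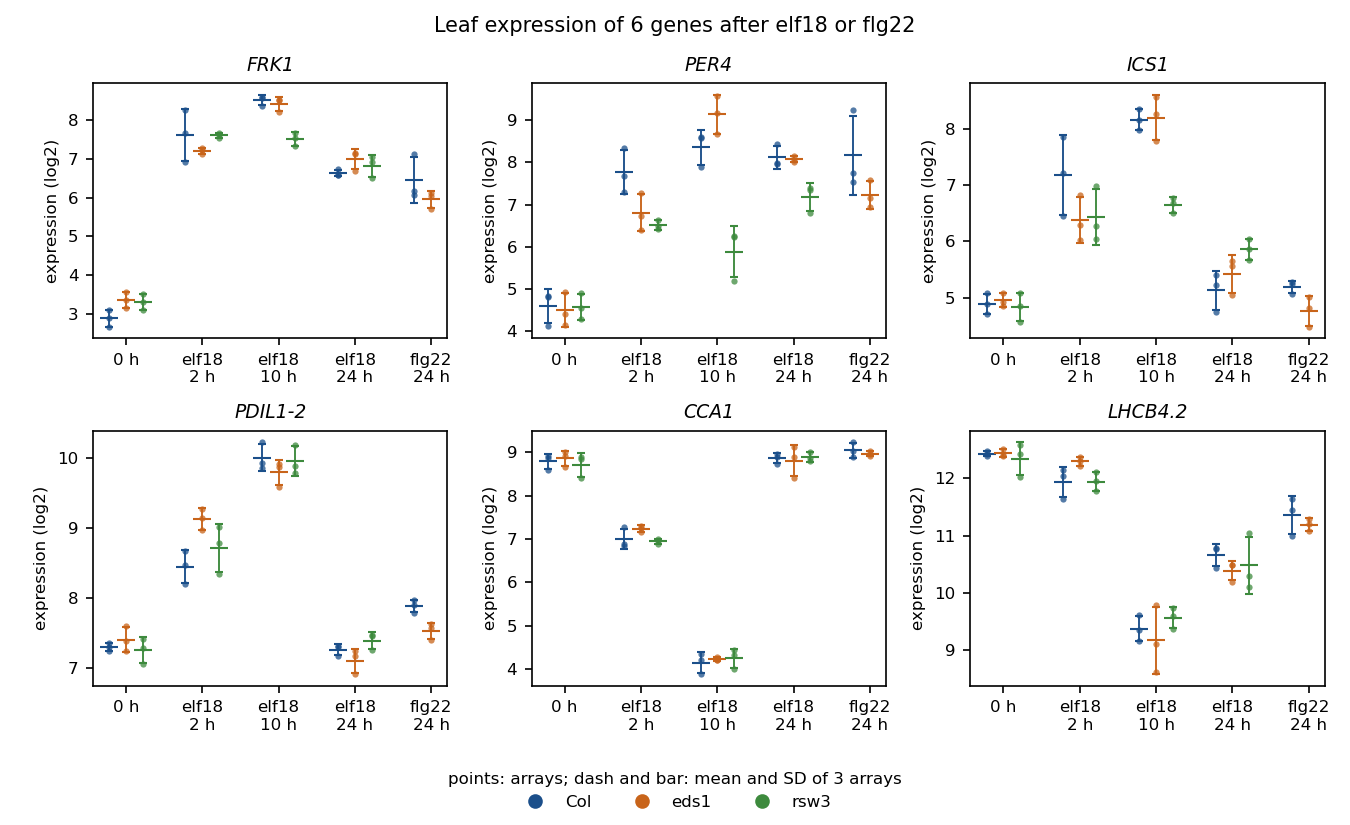
Log2 expression of 6 genes in leaves (vertical axes) at 0 h, after elf18 for 2, 10 and 24 h and after flg22 for 24 h (horizontal axes), with points for arrays and a dash and bar for the mean and SD of 3 arrays. FRK1, PER4, ICS1 and PDIL1-2 rise in each genotype by 10 h, PER4 and ICS1 least in rsw3 at that time, while CCA1 and LHCB4.2 fall by 10 h, and CCA1 is near its 0 h level at 24 h.

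The response of the mutants to elf18 was measured against their own 0 h controls. In eds1, FRK1 rose by 3.83 ± 0.23 at 2 h, 5.03 ± 0.23 at 10 h and 3.61 ± 0.23 at 24 h, from 3.37 ± 0.20 at 0 h. In rsw3 it rose by 4.28 ± 0.23, 4.19 ± 0.23 and 3.49 ± 0.23, from 3.32 ± 0.21. ICS1 rose by 3.25 ± 0.26 in eds1 and 1.81 ± 0.26 in rsw3 at 10 h, and CCA1 fell (-4.62 ± 0.15 and -4.45 ± 0.15). The chaperone gene BIP3 rose by 3.69 ± 0.31 in eds1 at 2 h (adjusted p = 9.19e-11) and by 2.17 ± 0.31 in rsw3. The salicylic acid responsive genes had a median of 2.05 in eds1 (adjusted p = 2.2e-17) and 1.70 in rsw3 (adjusted p = 3.34e-15) at 10 h. The endoplasmic reticulum list had medians of 0.83 (adjusted p = 2.09e-12) and 1.01 (adjusted p = 7.33e-14).

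In eds1 1254 genes rose and 1796 fell at 2 h, 1927 and 2619 at 10 h, and 2040 and 3002 at 24 h. In rsw3 1571 rose and 1563 fell at 2 h, 1994 and 2008 at 10 h, and 1787 and 2190 at 24 h. These counts are not tests of a difference between genotypes, and those differences were tested directly.

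The response to flg22 at 24 h was measured in Col and eds1 against 0 h. In Col, the camalexin gene CYP71A12 rose by 4.32 ± 0.49 from 4.32 ± 0.64 (adjusted p = 1.45e-08), the trypsin inhibitor gene TI1 by 4.17 ± 0.22 and the defensin gene PDF1.4 by 3.91 ± 0.22. In eds1 they rose by 3.02 ± 0.49, 3.35 ± 0.22 and 3.53 ± 0.22. LBD41, a transcription factor gene of the LOB domain family, rose by 3.54 ± 0.22 in Col and 4.27 ± 0.22 in eds1, where it had the largest rise among genes with a symbol. GASA6 fell in both (-4.54 ± 0.39 and -4.38 ± 0.39).

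In Col 2645 genes rose and 3043 fell after flg22, and in eds1 2241 rose and 3123 fell. The early pattern response genes had median 2.57, 8 of 8 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 6.51e-15 in Col, and median 2.02, 8 of 8 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 2.48e-12 in eds1. The 8 cell wall genes had median -0.96, 0 of 8 genes higher and 6 lower, the same counts adjusted over the list alone, adjusted p = 3.32e-14 in Col, and median -1.31, 0 of 8 genes higher and 6 lower, the same counts adjusted over the list alone, adjusted p = 1.03e-15 in eds1. The 2 senescence genes SAG13 and NAP were 3.33 ± 0.39 and 1.12 ± 0.13 higher in Col. The reference genes were lower in eds1 after flg22, with median -0.12, 0 of 4 genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.00654, or 0.486 with an estimated correlation.

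Whether leaves of the eds1 mutant differ from the wild type was tested at each time against the Col arrays of that time. At 0 h the loci AT2G43620 and AT1G65500 were higher in eds1 by 1.47 ± 0.14 (adjusted p = 1.79e-07) and 1.41 ± 0.19 (adjusted p = 0.000227), from 9.64 ± 0.34 and 8.59 ± 0.37 in Col. Both loci were chosen after their values were seen. At 10 h LBD41 was 2.64 ± 0.22 higher in eds1 (adjusted p = 4.37e-09), at 9.10 ± 0.28 against 6.47 ± 0.11 in Col, NRAMP3 was 1.00 ± 0.15 higher and PP2-B1 lower (-1.26 ± 0.17).

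At 0 h 4 genes were higher and 0 lower in eds1, with 737 at an unadjusted p under 0.05. Beside AT2G43620 and AT1G65500 these were AT2G44380, also chosen after its values were seen (0.75 ± 0.14), and CYP71B24 (0.90 ± 0.17). After quantile normalization 4 genes were higher and 1 lower. The count was 103 with array weights, 2 after centring and 2 without Col array 3 and 2 without eds1 array 2. CYP71B24 passed only with eds1 array 3 left out or with no array left out. Its adjusted p was 0.14, 0.11 and 0.237 without Col arrays 1, 2 and 3, and 0.082 and 0.529 without eds1 arrays 1 and 2. The adjusted p of AT2G44380 was 0.11 and 0.237 without Col arrays 2 and 3, and 0.337 and 0.0956 without eds1 arrays 2 and 3.

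At 2 h after elf18 22 genes were higher and 6 lower in eds1. Among called genes with a symbol and non-overlapping replicates, TED6 was furthest above Col (1.22 ± 0.20, adjusted p = 0.00998) and NF-YA3 furthest below (-0.61 ± 0.12, adjusted p = 0.0208). By fry the endoplasmic reticulum genes were higher, with median 0.27, 3 of 21 genes higher and 0 lower, 9 and 0 adjusted over the list alone, adjusted p = 0.0233, or 0.0773 with an estimated correlation, and the salicylic acid synthesis genes lower, with median -0.67, 0 of 5 genes higher and 0 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.0238, or 0.0773 with an estimated correlation. The guard cell markers had median 0.26, 0 of 5 genes higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.0238, or 0.0773 with an estimated correlation. No list passed with an estimated correlation. The count of 28 was 44 after quantile normalization, 450 with array weights and 60 with the 25th percentile of each array as a covariate, added after seeing the data. It rested on single arrays: 0 genes passed without eds1 array 2, 8 without eds1 array 1, 9 without eds1 array 3, 4 without Col array 1, 10 without Col array 3 and 78 without Col array 2. TED6 lost its call without Col array 3 (adjusted p = 0.0521) and eds1 array 2 (0.0972). NF-YA3 kept its call only without Col array 2, and had adjusted p = 0.225, 0.0521, 0.0633, 0.124 and 0.075 without Col arrays 1 and 3 and eds1 arrays 1, 2 and 3.

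At 10 h 5 genes were higher and 3 lower in eds1, or 62.5% higher, against 75.0% of 24 genes after quantile normalization and 80.0% of 5 after centring each array on its median. The count was 61 with array weights, 28 with the covariate and 5 without Col array 2. Among the higher genes were the loci AT3G10040 (1.83 ± 0.21, adjusted p = 3.19e-06) and AT1G33055 (1.00 ± 0.17), chosen after their values were seen. AT1G33055 lost its call without Col array 1 (adjusted p = 0.0826), eds1 array 1 (0.0676) and eds1 array 2 (0.095). The salicylic acid responsive genes had median -0.37, 0 of 10 genes higher and 0 lower, 0 and 1 adjusted over the list alone, adjusted p = 0.00512, and the 2 phloem markers had median -0.38, 0 of 2 genes higher and 0 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.00133.

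At 24 h after elf18 only MAPKKK13 (-0.84 ± 0.15) and NUDT6 (-0.75 ± 0.13) differed between eds1 and Col under limma with all arrays, both lower in eds1 (adjusted p = 0.038 and 0.0377), and 1042 genes had an unadjusted p under 0.05. NUDT6 lost its call without Col array 1 (0.14), Col array 3 (0.335) and eds1 array 3 (0.16). MAPKKK13 lost it without Col arrays 2 (0.238) and 3 (0.335) and eds1 arrays 1 (0.163) and 2 (0.0716). The count was then 1 without Col array 1, Col array 2 or eds1 array 3, 0 without Col array 3 and 6 without eds1 array 1, and 1 with array weights. No list passed by fry at 0 h or at 24 h. With only the arrays of the comparison, eds1 and Col differed in 0, 0, 1 and 0 genes at 0, 2, 10 and 24 h.

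At 24 h after flg22 10 genes were higher and 16 lower in eds1 than in Col, or 38.5% higher, against 54.5% after quantile normalization. GSTU12 was lower (-1.75 ± 0.24, adjusted p = 0.000357), IGMT4 lower (-1.44 ± 0.31, adjusted p = 0.0378) and CYP79B3, an enzyme that feeds tryptophan into camalexin and indole glucosinolates, lower (-1.03 ± 0.15, adjusted p = 0.000437). LBD41 was 1.03 ± 0.22 higher (adjusted p = 0.0378). The tryptophan, camalexin and indole glucosinolate list had median -0.34, 0 of 15 genes higher and 2 lower, 0 and 7 adjusted over the list alone, adjusted p = 0.00298. The senescence genes had median -0.91, 0 of 2 genes higher and 0 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.00298, and the cell wall genes median -0.12, 0 of 8 genes higher and 0 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.0427, or 0.0979 with an estimated correlation. Left out 1 at a time, Col arrays 1 and 3 and eds1 arrays 1, 2 and 3 gave 12, 10, 65, 7 and 8 genes. Array weights gave 73, and only the arrays of the comparison 0. IGMT4 kept its call only without eds1 array 1, and had adjusted p = 0.203, 0.0839, 0.117, 0.169 and 0.448 without Col arrays 1, 2 and 3 and eds1 arrays 2 and 3. LBD41 kept its call only without Col array 2, and had adjusted p = 0.235, 0.141, 0.0625, 0.169 and 0.0989 without Col arrays 1 and 3 and eds1 arrays 1, 2 and 3.

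Whether the response itself differed between eds1 and Col was tested as the difference of the 2 changes from 0 h. For elf18 the difference passed for 2 genes at 2 h, 7 at 10 h and 1 at 24 h, with 954, 882 and 791 at an unadjusted p under 0.05. LBD41 rose more in eds1 by 2.34 ± 0.31 at 10 h (adjusted p = 0.000126), from 6.26 ± 0.35 at 0 h in eds1 and 5.96 ± 0.14 in Col, and AT3G10040 by 1.72 ± 0.29. AT2G43620, higher in eds1 at 0 h, changed less there at every elf18 time, by -1.64 ± 0.20, -1.57 ± 0.20 and -1.40 ± 0.20. The same Col 0 h arrays enter the 0 h difference and these, with the opposite sign. No list passed by fry in these 3 tests.

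The counts of genes whose elf18 response differed in eds1 moved with the setting and with single arrays. With array weights they were 309, 43 and 2 at 2, 10 and 24 h, and with only the arrays of the comparison 0, 1 and 0. At 2 h the count was 1 without Col 0 h array 3, eds1 0 h array 2 or 3, Col 2 h array 3, or eds1 2 h array 1 or 2. It was 4 without Col 0 h array 2 and 42 without Col 2 h array 2. At 10 h it was 3 without Col 0 h array 3, eds1 0 h array 2 or eds1 10 h array 3, and 4 without Col 10 h array 2 or 3 or eds1 10 h array 2. At 24 h it was 2 without eds1 0 h array 1.

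For flg22 the response differed in 8 genes, all with a lower value in eds1, against 4 with a higher and 12 with a lower value after quantile normalization. CYP79B3 was lower (-1.39 ± 0.21, adjusted p = 0.00165), as was the copper/zinc superoxide dismutase gene CSD1 (-1.37 ± 0.23, adjusted p = 0.00523). The tryptophan, camalexin and indole glucosinolate list had median -0.53, 0 of 15 genes higher and 2 lower, 0 and 9 adjusted over the list alone, adjusted p = 0.00115, and the senescence genes median -1.27, 0 of 2 genes higher and 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.000343. Without 1 array the count was 5 (Col 0 h array 1), 3 (Col 0 h array 3), 4 (eds1 0 h array 2), 3 (Col flg22 array 1), 23 (eds1 flg22 array 1) and 4 (eds1 flg22 array 3). It was 67 with array weights, 12 with the covariate and 0 with only the arrays of the comparison.

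**Figure D2:**
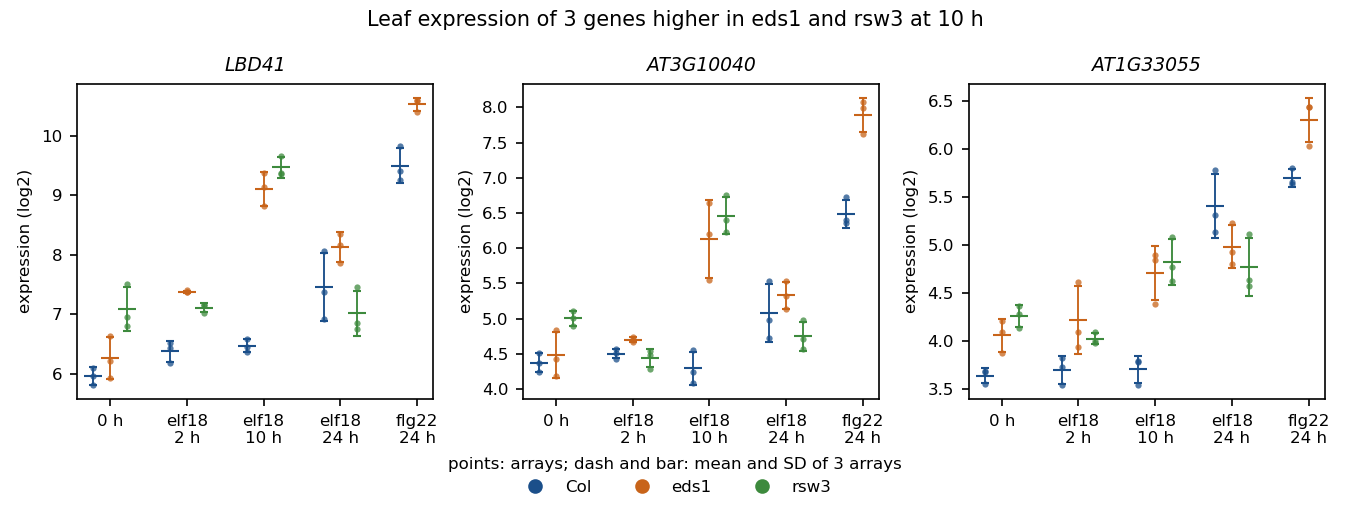
Log2 expression of LBD41, AT3G10040 and AT1G33055 (vertical axes) at 0 h, after elf18 for 2, 10 and 24 h and after flg22 for 24 h (horizontal axes), with points for arrays and a dash and bar for the mean and SD of 3 arrays. At 10 h after elf18 all 3 are higher in eds1 and rsw3 than in Col.

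Whether leaves of the rsw3 mutant differ from the wild type, at 0 h or in their response to elf18, was tested against the same Col arrays that served for eds1. At 10 h after elf18 PER4, a peroxidase gene, was lower (-2.46 ± 0.35) in rsw3 (adjusted p = 6.07e-05), at 5.89 ± 0.61 against 8.35 ± 0.41 in Col, with 4.58 ± 0.31 and 4.59 ± 0.41 at 0 h. CYP71A12 was lower (-2.53 ± 0.49, adjusted p = 0.00232), the ethylene synthesis gene ACS2 lower (-1.87 ± 0.19, adjusted p = 4.2e-07), ICS1 lower (-1.51 ± 0.26, adjusted p = 0.000632), ZAT11 lower (-1.88 ± 0.28) and STZ lower (-1.59 ± 0.19). LBD41 was 3.00 ± 0.22 higher in rsw3 (adjusted p = 1.43e-10) and AT3G10040, chosen after its values were seen, 2.17 ± 0.21 higher. The jasmonate synthesis gene AOC2 was 1.01 ± 0.21 higher.

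At 10 h 145 genes were higher and 381 lower in rsw3, or 27.6% higher, against 43.2% of 706 genes after quantile normalization. The count was 1404 with array weights and 860 with the covariate. RTFL20 was 2.00 ± 0.51 higher, PnsL3 1.16 ± 0.21 and CAX1 1.11 ± 0.23. Left out 1 at a time, Col arrays 1 and 3 and rsw3 arrays 2 and 3 gave 292, 199, 262 and 231 genes. RTFL20 had adjusted p = 0.0595, 0.141, 0.147 and 0.0616 without Col arrays 2 and 3 and rsw3 arrays 1 and 2. On simulated data for this comparison, with 200 of 15856 genes changed in 60 simulations, 36.9% of changes of 0.5, 83.7% of changes of 1 and 98.3% of changes of 2 (log2) were found. Averaged over the simulations 4.25% of calls were false, with a median of 3 false calls and a highest of 62.

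In rsw3 at 10 h, 8 lists were lower than in Col by fry. The salicylic acid responsive genes had median -0.45, 0 of 10 genes higher and 5 lower, the same counts adjusted over the list alone, adjusted p = 5.72e-05, and the salicylic acid synthesis genes median -0.47, 0 of 5 genes higher and 1 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.00205. The early pattern response genes had median -0.58, 1 of 8 genes higher and 3 lower, 1 and 7 adjusted over the list alone, adjusted p = 0.000391, and the receptors and early signalling median -0.35, 0 of 12 genes higher and 2 lower, 0 and 7 adjusted over the list alone, adjusted p = 0.00161. The tryptophan, camalexin and indole glucosinolate list had median -0.49, 0 of 15 genes higher and 4 lower, 0 and 9 adjusted over the list alone, adjusted p = 0.000349. The N-hydroxypipecolic acid pathway had median -0.73, 0 of 3 genes higher and 2 lower, the same counts adjusted over the list alone, adjusted p = 0.00202, the senescence genes median -0.85, 0 of 2 genes higher and 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.000369 and the phloem markers median -0.31, 0 of 2 genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.00286, or 0.0801 with an estimated correlation. The endoplasmic reticulum list did not pass, with median -0.04, 0 of 21 genes higher and 0 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.522.

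The change from 0 h to 10 h after elf18 differed between rsw3 and Col in 176 genes, 49 with a higher and 127 with a lower value in rsw3, and in 1874 at an unadjusted p under 0.05. Among the named genes with the largest differences, the calls that held with any 1 array left out were those of PER4 (-2.45 ± 0.49, adjusted p = 0.00901), ACS2 (-1.80 ± 0.28, adjusted p = 0.000689), ARPN (-1.68 ± 0.30, adjusted p = 0.00315), the transcription factor gene RAV1 (-1.68 ± 0.25, adjusted p = 0.000567), HB2 (0.91 ± 0.19), RAD51C (0.91 ± 0.16), EMB3108 (0.87 ± 0.18) and LBD41. LBD41 was higher by 1.88 ± 0.31 (adjusted p = 0.0017). RAV1 and RAD51C differed from Col already at 0 h. RAV1 then stood at 7.14 ± 0.30 in rsw3 against 5.84 ± 0.09 in Col, and RAD51C was lower in rsw3 (-0.57 ± 0.11). Most of the difference in response of RAV1 and RAD51C thus lay at 0 h. By fry 8 lists were lower in rsw3 in this test, among them the salicylic acid responsive genes, with median -0.54, 0 of 10 genes higher and 2 lower, 0 and 6 adjusted over the list alone, adjusted p = 0.00036, and the early pattern response genes, with median -0.75, 0 of 8 genes higher and 3 lower, 0 and 6 adjusted over the list alone, adjusted p = 0.00333. These were the 2 that passed with an estimated correlation, and the other 6 lost their call (adjusted p from 0.0645 to 0.161). The count was 275 after quantile normalization, 763 with array weights and 424 with the covariate, and 85 without Col 0 h array 3, 114 and 75 without Col 10 h arrays 1 and 3, and 89 and 98 without rsw3 10 h arrays 2 and 3. On simulated data for this test 12.7%, 62.6% and 93.9% of changes of 0.5, 1 and 2 were found. Averaged over the simulations 4.57% of calls were false, with a median of 4 false calls and a highest of 76.

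**Figure D3:**
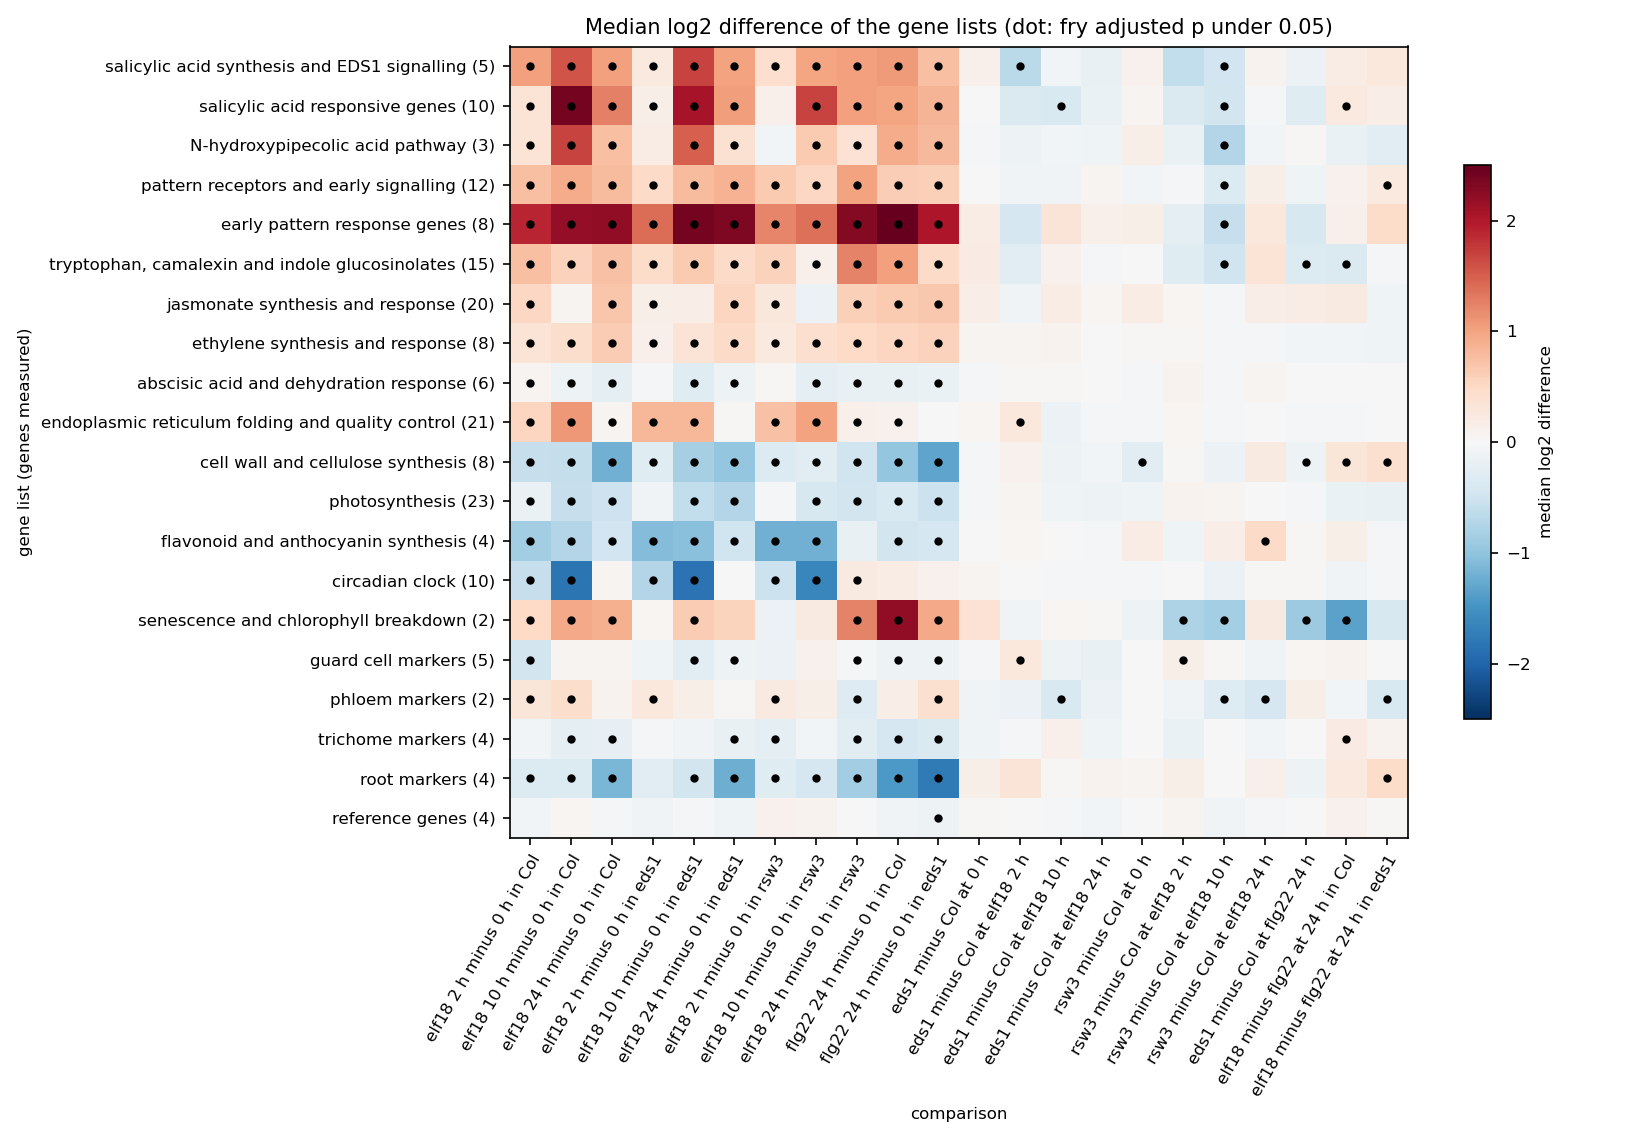
Median log2 difference of the 20 gene lists (vertical axis, with the number of genes measured) in 22 comparisons (horizontal axis), from blue for lower to red for higher, with a dot where fry gave an adjusted p under 0.05. Defence lists are red after both peptides, and at 10 h after elf18 8 lists are lower in rsw3 than in Col.

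At 0 h 10 genes were higher and 9 lower in rsw3 than in Col. RAV1 was higher, at 7.14 ± 0.30 against 5.84 ± 0.09 in Col (adjusted p = 0.000197), and LBD41 1.13 ± 0.22 higher (adjusted p = 0.02). The ethylene-forming enzyme gene EFE was lower (-0.59 ± 0.11). AT2G43620 and AT1G65500, the loci higher in eds1, were also 1.05 ± 0.14 and 1.02 ± 0.19 higher in rsw3, against the same Col arrays. The cell wall list had median -0.28, 0 of 8 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 0.0327, or 0.115 with an estimated correlation. The count was 152 with array weights, 45 with the covariate, 1 with only the arrays of the comparison, 2 without Col array 3 and 10 without rsw3 array 2. LBD41 had adjusted p = 0.0748 and 0.223 without Col arrays 2 and 3 and 0.137 without rsw3 array 3. EFE had 0.221 and 0.101 without Col array 3 and rsw3 array 2, and AT1G65500 had 0.3, 0.0555 and 0.0552 without Col array 3 and rsw3 arrays 1 and 2.

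At 2 h after elf18 3 genes were higher and 1 lower in rsw3, against 5 and 0 after centring each array on its median, and 828 had an unadjusted p under 0.05. MLP-300B was 1.50 ± 0.21 higher (adjusted p = 0.001), TED6 1.18 ± 0.20 higher and SKL1 lower (-0.52 ± 0.09), and the locus AT1G52050, chosen after its values were seen, was 1.63 ± 0.27 higher. MLP-300B, TED6 and AT1G52050 were also called higher in eds1 at 2 h, against the same Col arrays (1.17 ± 0.21, 1.22 ± 0.20 and 1.52 ± 0.27). Their SD was 0.51, 0.57 and 0.58 in those Col arrays, against 0.18, 0.09 and 0.28 in rsw3. The senescence genes had median -0.77, 0 of 2 genes higher and 0 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.0109, and the guard cell markers median 0.14, 0 of 5 genes higher and 0 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.0139. The count was 52 with array weights, 7 with the covariate, 0 with only the arrays of the comparison, 14 without Col array 2, 2 without Col array 3 and 1 without rsw3 array 2 or 3. TED6, SKL1 and AT1G52050 had adjusted p = 0.146, 0.149 and 0.146 without Col array 3, 0.113, 0.206 and 0.0957 without rsw3 array 2, and 0.0598, 0.256 and 0.0951 without rsw3 array 3. SKL1 had 0.0864 without Col array 1.

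The elf18 2 h response differed between rsw3 and Col in 1 gene, RHA3A (-0.71 ± 0.12, adjusted p = 0.0191), or 0.0% higher, against 33.3% of 6 genes after quantile normalization, and 1172 genes had an unadjusted p under 0.05. RHA3A stood at 7.06 ± 0.10 in rsw3 against 6.56 ± 0.07 in Col at 0 h, and at 6.91 ± 0.10 against 7.12 ± 0.05 at 2 h. Most of its difference in response thus lay at 0 h. No list passed by fry. Without Col 0 h array 3, rsw3 0 h array 1 or 2, Col 2 h array 1, or rsw3 2 h array 2 or 3, no gene passed, and the adjusted p of RHA3A was 0.137, 0.0955, 0.0729, 0.116, 0.0527 and 0.139. The count was 83 with array weights, 4 with the covariate, 0 after centring or with only the arrays of the comparison, 4 without Col 0 h array 1, 2 without rsw3 0 h array 3, 5 without Col 2 h array 2 and 3 without Col 2 h array 3.

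At 24 h after elf18 155 genes were higher and 75 lower in rsw3 than in Col, or 67.4% higher, against 53.4% after quantile normalization. The count of 230 was 1 with only the arrays of the comparison and 421 with the covariate. Among the named genes whose calls held with any 1 array left out, PS2, a phosphatase gene, was higher, at 7.15 ± 0.42 against 5.04 ± 0.59 in Col (adjusted p = 0.000847), as was the defensin gene LCR67, at 7.58 ± 0.49 against 5.47 ± 0.48 (adjusted p = 0.00394). PAP1, an activator of anthocyanin synthesis, was 1.60 ± 0.25 higher (adjusted p = 0.000412), from 3.13 ± 0.18 in Col at 24 h. NUDT6 was lower (-1.17 ± 0.13, adjusted p = 6.83e-06) and ARD3 lower (-1.30 ± 0.32). The flavonoid and anthocyanin list had median 0.47, 2 of 4 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 0.00124, or 0.05 with an estimated correlation, and the phloem markers median -0.41, 0 of 2 genes higher and 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.000501. The count was 142, 141 and 152 without Col arrays 1, 2 and 3, and 63 without rsw3 array 1. ARD3 had adjusted p = 0.295 without Col array 2, and 0.105, 0.118 and 0.0573 without rsw3 arrays 1, 2 and 3.

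The elf18 24 h response differed between rsw3 and Col in 167 genes, 109 with a higher and 58 with a lower value in rsw3, or 65.3% higher, against 48.1% after quantile normalization. The count was 5 with only the arrays of the comparison, 95 after centring, 486 with array weights and 384 with the covariate. UGT74E2 was higher by 2.75 ± 0.57 (adjusted p = 0.0151) and PS2 by 2.33 ± 0.48 (adjusted p = 0.0151). NUDT6, the only named gene whose call held with any 1 array left out, was lower (-1.34 ± 0.18, adjusted p = 0.000298). The cell wall list had median 0.64, 1 of 8 genes higher and 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 0.00199, or 0.0711 with an estimated correlation. The count was 78 and 37 without Col 0 h arrays 2 and 3, 81 without rsw3 0 h array 2, 109 and 63 without Col 24 h arrays 1 and 3, and 34 without rsw3 24 h array 1. UGT74E2 had adjusted p = 0.0554, 0.0522, 0.0562 and 0.0505 without Col 0 h array 3, rsw3 0 h array 2, Col 24 h array 3 and rsw3 24 h array 1. PS2 had 0.0757, 0.0571 and 0.0654 without Col 0 h array 3, Col 24 h array 3 and rsw3 24 h array 1.

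No gene differed from Col with the same sign at all 4 times from 0 to 24 h, in eds1 or in rsw3, under limma with all arrays. In eds1 41 genes and in rsw3 742 genes differed at 1 or more of these times.

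elf18 and flg22 were compared with each other at 24 h after treatment. The labels do not say whether both sets were sampled at the same time of day or in the same experiment. Since the titles of the flg22 arrays differ in style, the peptide and a separate experiment cannot be told apart here. In Col, NUDT6 was 1.80 ± 0.13 higher after elf18 (adjusted p = 1.32e-10), at 7.10 ± 0.20 against 5.30 ± 0.13 and 4.91 ± 0.10 at 0 h. The peptide gene IDA was 1.57 ± 0.21 higher after elf18 (adjusted p = 3.6e-05). LCR67, SAG13 and LBD41 were lower after elf18, by log2 differences of -2.24 ± 0.40, -2.05 ± 0.39 and -2.05 ± 0.22 (adjusted p = 0.00134, 0.0024 and 7.64e-07). CYP71A12 was lower (-2.30 ± 0.49), and had adjusted p = 0.0921 without Col elf18 array 3 and 0.0598 without Col flg22 array 2. In eds1, MLP28 was 2.08 ± 0.21 and PNP-A 1.50 ± 0.31 higher after elf18, and LBD41 lower (-2.40 ± 0.22, adjusted p = 1.29e-08).

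In Col 176 genes were higher and 194 lower after elf18 than after flg22, or 47.6% higher, against 57.8% after quantile normalization. In eds1 381 were higher and 189 lower. With only the arrays of the comparison the counts of 370 and 570 were 12 and 7, and with the covariate 694 and 1070, and array weights gave 751 in Col. By fry 3 lists were higher and 2 lower after elf18 than after flg22 in Col, and 3 higher and 1 lower in eds1. With an estimated correlation 1 list passed in Col and 0 in eds1. Given here are the lower lists in Col and some of the higher ones in eds1. In Col the senescence genes had median -1.33, 0 of 2 genes higher and 2 lower, the same counts adjusted over the list alone, adjusted p = 1.31e-05. The tryptophan, camalexin and indole glucosinolate list had median -0.37, 0 of 15 genes higher and 4 lower, 0 and 5 adjusted over the list alone, adjusted p = 0.00947, or 0.112 with an estimated correlation. In eds1 the cell wall list had median 0.40, 4 of 8 genes higher and 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 0.00087, or 0.0774 with an estimated correlation, and the root markers median 0.47, 2 of 4 genes higher and 0 lower, the same counts adjusted over the list alone, adjusted p = 0.0368, or 0.341 with an estimated correlation. In Col the count was 167 and 178 without elf18 arrays 1 and 3, and 185 and 182 without flg22 arrays 2 and 3. In eds1 it was 303 and 328 without flg22 arrays 2 and 3. Whether the peptides differ more in eds1 than in Col was not tested here.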

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

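Of the tests in this part, those of low oxygen, of the slopes, of the array spread in the splits and of the median of the defence genes were chosen only after the result was seen.

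The difference between the mutant and the Col change from 0 h was tested gene by gene, and some genes passed in each of 7 tests. For elf18 in eds1 they were 2 at 2 h, 7 at 10 h and 1 at 24 h, and for flg22 in eds1 8. For elf18 in rsw3 they were 1 at 2 h, 176 at 10 h and 167 at 24 h. Each was compared with 100 splits of the same arrays, the real one included. As many genes were called in 11 splits for eds1 at 2 h (real 2, highest other 384), 22 for eds1 at 24 h (real 1, highest other 17) and 18 for rsw3 at 2 h (real 1, highest other 18), so chance is not excluded for these 3. It was 1 split for eds1 at 10 h (real 7, highest other 4), 2 for rsw3 at 10 h (real 176, highest other 280), 1 for rsw3 at 24 h (real 167, highest other 47) and 1 for flg22 in eds1 (real 8, highest other 7). The margins of 7 against 4 and 8 against 7 are narrow. The other splits were a random draw, and the 7 tests were not corrected for their number. The splits exchange genotypes within a time, so they test for any genotype difference and not for an equal response. Splits that mix the genotypes also carry any real genotype difference in their spread. For rsw3 at 2 and 24 h the highest other split kept the genotypes together and exchanged all 3 arrays at 0 h. It thus adds up the genotype differences of the 2 times. For the last 4 tests the share was under 0.05, which argues against a chance assignment of genotypes but does not exclude it. With the 25th percentile as a covariate, as many genes as in the real split were called in 15, 20 and 4 splits for the first 3 and in 1, 1, 1 and 2 for these 4, where for flg22 the real split called 12 and the highest other 34. The split with 384 genes is many times the real count and points to a structure of the samples. Of the 99 other splits it had the largest difference in the standard deviation of the arrays (0.212, against 0.0162 in the real one), and with the 25th percentile as a covariate it called 0 genes and the real one 2. Over the 99 splits the count followed this difference only weakly (Spearman 0.144, and 0.112 for rsw3 at 10 h), so this is given for the highest split alone. Residual component 1 held 17.5% of the residual variance and correlated at 0.917 with that standard deviation. The split with 280 kept the 10 h genotypes together, exchanged 2 of the 3 arrays at 0 h and also had the largest such difference (0.15, against 0.00902), and with the covariate it called 112 and the real one 424.

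Gene lists also differed in these tests by fry. At 10 h after elf18 8 lists had a lower response in rsw3 than in Col: salicylic acid synthesis and EDS1 signalling (adjusted p = 0.0103, 0.0645 with an estimated correlation), salicylic acid responsive genes (0.00036), N-hydroxypipecolic acid pathway (0.0103, 0.0645), pattern receptors and early signalling (0.0332, 0.14), early pattern response genes (0.00333), tryptophan, camalexin and indole glucosinolates (0.0103, 0.0645), senescence (0.0103, 0.0645) and phloem markers (0.0339, 0.161). At 24 h the cell wall list had a higher (0.00199, 0.0711) and the phloem markers a lower response (0.0137, 0.167). After flg22 the tryptophan, camalexin and indole glucosinolate list (0.00115) and the senescence genes (0.000343) had a lower response in eds1. Among the 370 control probe sets, which no comparison uses, 18 changed from 0 h to 24 h after flg22 in Col, or 4.87% against 35.9% of the genes.

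LBD41, AT3G10040 and AT1G33055 were higher in both mutants than in the same Col arrays at 10 h after elf18. The signal range of the arrays is argued against, since with the 25th percentile as a covariate the smallest of the 6 differences was 1.07. A single deviating array is argued against by a smallest difference of 0.91 with 1 array left out, though AT1G33055 then lost its call in eds1 without Col array 1 (adjusted p = 0.0826) and eds1 arrays 1 (0.0676) and 2 (0.095). Low oxygen in the mutant leaves at sampling may play a part, since the list of the 18 other low-oxygen genes tested higher in eds1 (median 0.32, p = 0.0132, 16 above Col but 0 passing singly) and in rsw3 (median 0.19, p = 0.0438, or 0.158 with an estimated correlation, 13 above Col and 4 passing), while their difference in response from 0 h did not pass (p = 0.202 in eds1 and 0.379 in rsw3). From 0 h to 10 h after elf18 these 18 genes did not rise as a set in either mutant. Their mean change was -0.57 in Col, -0.32 in eds1 and -0.38 in rsw3, with medians of -0.10, 0.11 and -0.10. Called higher and lower were 6 and 7 genes in Col, 6 and 6 in eds1, and 5 and 6 in rsw3. In the mean they thus fell less in the mutants than in Col. No group was sampled under a known oxygen level, so handling and an effect of the mutations stay open.

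Defence genes responded less to elf18 in rsw3 than in Col at 10 h, with a median difference of -0.53 over 53 genes. A scale compressed alike for all genes in the rsw3 arrays is argued against, but only by the 10 clock genes. For them the slope of the rsw3 change on the Col change was 0.97. It was 0.65 for the 36 of the 53 defence genes that changed in eds1 at 10 h, whose arrays do not enter the slope. The difference was 0.321 (SE 0.0502 from resampling genes and 0.0332 from a jackknife over the 12 arrays). Its lowest value was 0.308 with 1 array left out, and it was 0.318 corrected for noise in Col. The smaller slope was not special to defence. It was 0.73 for the 1927 genes that rose and 0.85 for the 2619 that fell in eds1 at 10 h. Compression is thus not excluded beyond the clock genes, and the slopes were not computed again after quantile normalization. The signal range is argued against, since 176 of 176 genes stayed called with the 25th percentile as a covariate. For the count the drop itself cannot decide on a single deviating array, since it fell from 176 to between 75 and 164 with any 1 array left out. The lowest count, 75, came without Col 10 h array 3, whose residual standard deviation of 0.167 was the lowest of all arrays. This argues against that array as a deviating one. For the median a single deviating array is argued against, since the median was -0.45 at its nearest to 0, without rsw3 0 h array 3. An effect of the rsw3 mutation and a shift in the timing of the response stay open and were not tested.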

How the results depend on the processing

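The names as deposited, the 25th percentile covariate and the fit without array 2 of eds1 at 24 h after elf18 were chosen after seeing the data. Except where a value itself shows it, the cause was not tested. Counts are given where they left 1.5 times the reported count.

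Of 1023 values of named genes, 1 changed sign under an alternative other than the names: ACT2 at 24 h after elf18 in eds1 was 0.01 with quantile normalization, against -0.19. The call was lost in 32 other values with quantile normalization, 59 with centring, 28 with a replicate block, 15 without the array that stood apart, 10 with array weights, 5 with the covariate, 1 with trend and robust variance and 275 with only the arrays of the comparison, and in 0 with the mean of probe sets or the other deposited table, and 0 of 1018 without the dim probe sets. With 1 array left out 1049 of 6516 refitted values lost the call, and these belonged to 270 of the 1023 values of named genes. With the names as deposited 172 of the 1023 values were called in their direction. With the names as deposited, the other table or the mean of probe sets, every count of genes stayed within 1.5 times. These counts could hardly move and say nothing on whether the names are right. Moving the names leaves the values of the rows as they are, the other table holds the same values, and only 72 genes have more than 1 probe set.

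Quantile normalization gave 44 genes for eds1 against Col at 2 h and 24 at 10 h, and for the difference in response 6 for rsw3 at 2 h, 275 for rsw3 at 10 h and 16 for flg22 in eds1. Centring gave 2 for eds1 against Col at 0 h and 5 at 10 h, and 1 for the eds1 response at 2 h, 0 for rsw3 at 2 h and 95 for rsw3 at 24 h. Without the dimmest 30% of probe sets there were 45 for eds1 at 2 h, 15 at 10 h, 7 for rsw3 at 2 h, 4 for the eds1 response at 2 h and 15 for that to flg22. The replicate block gave 1 for the eds1 response at 2 h. Trend and robust variance gave 14 for eds1 at 10 h, 7 for rsw3 at 2 h, 2 for the rsw3 response at 2 h and 16 for the eds1 response to flg22. The fit without the array that stood apart gave 7 for rsw3 at 2 h.

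Array weights gave 103, 450, 61 and 1 for eds1 against Col at 0, 2, 10 and 24 h and 73 after flg22, and 152, 52 and 1404 for rsw3 at 0, 2 and 10 h. For the differences in response they gave 309, 43 and 2 for eds1 at 2, 10 and 24 h, 83, 763 and 486 for rsw3, and 67 for flg22 in eds1, and 751 for elf18 against flg22 in Col. The 25th percentile covariate gave 60 and 28 for eds1 at 2 and 10 h, 45, 7, 860 and 421 for rsw3 at 0, 2, 10 and 24 h, 4, 424 and 384 for the rsw3 responses, and 694 and 1070 for elf18 against flg22 in Col and eds1.

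With only the arrays of a comparison, which leaves fewer arrays to measure the spread, elf18 gave 2039 at 2 h in Col and 3188 at 24 h in eds1. eds1 against Col gave 0, 0, 1 and 0 at 0, 2, 10 and 24 h and 0 after flg22, and rsw3 gave 1, 0 and 1 at 0, 2 and 24 h. The responses gave 0, 1 and 0 for eds1, 0 and 5 for rsw3 at 2 and 24 h and 0 for flg22, and elf18 against flg22 gave 12 in Col and 7 in eds1. A 2-fold change as well, a stricter demand by construction, gave for elf18 at 2, 10 and 24 h 692, 1216 and 1154 in Col, 565, 1158 and 1009 in eds1, and 595, 889 and 723 in rsw3, and for flg22 1299 and 1138. It gave 2, 5, 3 and 0 for eds1 against Col and 9 after flg22, 6, 68 and 45 for rsw3 at 0, 10 and 24 h, 0, 72 and 65 for the rsw3 responses, and 65 and 73 for elf18 against flg22.

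With 1 array left out the counts ranged as follows: eds1 against Col 2 to 6 at 0 h, 0 to 78 at 2 h, 5 to 9 at 10 h, 0 to 6 at 24 h and 7 to 65 after flg22, rsw3 2 to 21, 1 to 14, 199 to 409 and 63 to 185 at 0, 2, 10 and 24 h. The eds1 responses ranged from 1 to 42, 3 to 10 and 1 to 2, and 3 to 23 for flg22, the rsw3 responses from 0 to 5, 75 to 164 and 34 to 173, and elf18 against flg22 from 167 to 360 in Col and 303 to 530 in eds1. The 11 counts against 0 h stayed within 1.5 times. Of 580 list tests 216 passed by fry, 196 with the preset and 80 with the estimated correlation, and 216 with a replicate block. The lists were not tested again under the other alternatives, quantile normalization and leaving out arrays among them. Signal over background was examined only by leaving out the dimmest probe sets. No scaling moved the median of all genes by more than 0.1.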

Other observations

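The tests of low-oxygen and clock genes in this part were chosen only after the result was seen, and the splits were planned. Many low-oxygen genes rose at 24 h after both peptides in Col and eds1 and after elf18 in rsw3. In rsw3 AT1G33055 rose (0.51 ± 0.17, adjusted p = 0.0275), LBD41 (-0.07 ± 0.22, adjusted p = 0.884) and AT3G10040 (-0.26 ± 0.21, adjusted p = 0.432) did not pass, and the whole list of 21 genes had p = 0.0729 with an estimated correlation in limma camera, though fry gave 0.000112. LBD41 was higher in rsw3 than in Col at 0 h (1.13 ± 0.22, adjusted p = 0.02), and at 24 h the difference did not pass (-0.43 ± 0.22, adjusted p = 0.475). Its difference in elf18 24 h response between rsw3 and Col did pass (-1.56 ± 0.31, adjusted p = 0.0097). In that test 2 of the 21 genes were called lower and 0 higher. Without LBD41, AT3G10040 and AT1G33055 the other 18 genes had a median change of 0.83 in Col after elf18 (16 genes higher and 0 lower), 0.61 in eds1 (14 genes higher) and 0.67 in rsw3 (11 of 18 genes higher). After flg22 the medians were 0.89 in Col (16 genes higher) and 1.27 in eds1 (17 genes higher). The difference in the elf18 response between rsw3 and Col did not pass for the 18 genes (fry p = 0.105, or 0.155 with an estimated correlation), and for all 21 genes fry gave 0.0249, or 0.06 with an estimated correlation. Against 0 h and with an estimated correlation, p of the 18 genes was 0.0184, 0.0472, 0.0392, 0.00846 and 0.00541.

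The clock list changed at 10 h after elf18 in each genotype, with CCA1 and LHY lower and ELF4 higher, but the list lost its call with an estimated correlation (adjusted p = 0.0955 in Col, 0.0693 in eds1 and 0.0781 in rsw3). If the time of day set their level, they would be back near the 0 h level at 24 h, and the median absolute change at 24 h was at most 0.0839 of that at 10 h (eds1), with 0.0481 in Col and 0.0728 in rsw3. The time of day at sampling is thus a candidate explanation. A response to elf18 itself cannot be told apart from it, since there were 0 groups of peptide-free leaves after 0 h.

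In the comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05, and as many genes were called in 1 split, the real one, except where given. The real count and the highest of the other splits were, for elf18 at 2, 10 and 24 h against 0 h, 3365 and 2, 4580 and 0, and 5394 and 0 in Col, 3050 and 0, 4546 and 1, and 5042 and 1 in eds1, and 3134 and 1, 4002 and 0, and 3977 and 2 in rsw3. For flg22 they were 5688 and 0 in Col and 5364 and 0 in eds1. For eds1 against Col they were 4 and 1 at 0 h, 28 and 2 at 2 h, 8 and 0 at 10 h, 2 and 1 at 24 h, and 26 and 30 after flg22, where 2 splits called as many genes. For rsw3 against Col they were 19 and 1 at 0 h, 4 and 0 at 2 h, 526 and 0 at 10 h, and 230 and 1 at 24 h. For elf18 against flg22 they were 370 and 65 in Col and 570 and 6 in eds1.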
